A study of Ovis aries with 19 samples.

How the data were processed

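The series measured the transcriptomes of liver and muscle from 10 female sheep, 5 controls and 5 exposed to excess testosterone before birth. Total RNA of each tissue was made into libraries with a TruSeq kit, per the labels' protocols. Liver gave 4 control and 5 treated libraries, because no liver library of control sheep 132 was used here, and muscle gave 5 and 5. Group and sheep number came from the labels, so each replicate was a separate animal. Reads were trimmed with Trimmomatic, aligned with STAR and counted per gene with featureCounts 1.6.1, per the submitters' processing notes. The genome build, the annotation and the strand setting were not given in the sources used here.

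The deposited signal was a normalized read count per gene and library, for 28524 gene identifiers, of which 10441 were LOC identifiers. The scaling was read from the values. Within a library the values were whole multiples of what 1 read was worth, and 100% of them came out as whole reads within a tolerance of 0.01 read. Size factors recomputed from those reads by the median of ratios, within each tissue, differed from the deposited scaling by a relative 1.2e-10 at most. Levels were therefore comparable within a tissue. Between tissues they were set side by side only to check the tissue labels and to tell silent from expressed genes. Recovered reads per library ran from 10236600 to 16046300 in liver and from 8455560 to 14331600 in muscle. Identifiers were looked up in an NCBI gene table of the sheep assembly ARS-UI_Ramb_v3.0, where 22250 matched by symbol, 458 matched by gene number and 5816 did not match. That table was used for names and biotypes, and no coordinates are given because the build of the deposited values is unknown.

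Each gene with a mean of at least 10 in a tissue was tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Each tissue was fitted on its own libraries. The difference between tissues was the difference of both treatment effects in a fit of all 19 libraries, over genes past the filter in both tissues. Spearman's correlation of the treatment effects was taken over the same genes. The recovered reads were also tested with edgeR 4.0.16 and DESeq2 1.42.0 as alternatives. The sheep number pairs the libraries of both tissues, since they came from the same animal. Deviations from the group means correlated within a sheep at a median of 0.177, against a median of -0.0194 between different sheep, and 7 of 9 sheep correlated best with their own other tissue.

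The 57 gene lists, the tests, the alternatives not named below as added, and the rule for named genes were chosen before the data were examined. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and adjusted over the lists tested in that tissue. Camera with an estimated correlation and fry were alternatives. The named genes were, per tissue, the 8 largest changes in each direction among genes past the threshold, the smallest unadjusted p-values until 5 genes were named per direction, the 3 members with the smallest p in each list past the camera threshold, and fixed genes of hormone, insulin and energy metabolism. Some genes named by this rule are not reported here. Up to 5 genes past the threshold were named for the difference between tissues. Further alternatives were pseudocounts of 0.25 and 4, no filter, a mean of at least 50, TMM and median-of-ratios rescaling, array weights, robust shrinkage, 1 fit of all libraries, the sheep as a block, and each library or sheep left out in turn. Cyclic loess scaling and the tests of list differences between tissues, of long non-coding RNAs and of genes detected per library were added after seeing the data. So were the group means without 1 library, which are given for the 14 of 108 named gene and tissue pairs whose ratio of means moved by over 1.5 times. Genes detected were counted after thinning each library to 8000000 reads, or to 5000000 where the 50 most abundant genes were left out. For model results 100 splits of the libraries, or reassignments of the sheep, were compared, the real one included.

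The procedure was tested on simulated counts drawn from the real means and library sizes. For the test within each tissue, 33 or 34 genes were changed by 2, 4 and 8 times in each direction. In the liver simulation of 13592 genes, limma recovered 17.6% of the 2-fold increases and 91.2% of the 4-fold increases with 4 false calls, while DESeq2 made 33 false calls. In the muscle simulation of 12971 genes, limma recovered 70.6% of the 2-fold increases and 97.1% of the 4-fold increases with 13 false calls, and DESeq2 made 31. For the difference between tissues, simulated on 11662 genes, 2.94% of the 2-fold and 67.6% of the 4-fold increases were recovered. A simulated list shift of -0.50 in liver was called at a camera adjusted p of 5.1e-05, with 0 of the other lists called. The simulated genes were drawn independently, so this does not show how often camera calls lists whose genes move together. Splits of the real libraries other than by treatment gave a median of 9 lists called in each tissue.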

Results

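RNA of liver and muscle was sequenced from female sheep to compare animals exposed to excess testosterone before birth with control animals. Liver libraries came from 4 control and 5 treated sheep and muscle libraries from 5 control and 5 treated sheep. Total reads per library lay between 10236600 and 16046300 in liver and between 8455560 and 14331600 in muscle. The tissue labels matched the marker genes. The normalized read count of ALB, the albumin gene, was at least 112956 in each liver library and at most 16.2 in muscle, and that of ACTA1, the skeletal muscle actin gene, was at least 154279 in each muscle library and at most 9.12 in liver. Libraries of the same group differed by more than sampling noise in all 36 pairs, with a chi-square per degree of freedom of at least 23.7. The median residual SD was 0.52 on the log2 scale in liver and 0.31 in muscle. The labels named no batch within a tissue.

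The first comparison asked which liver transcripts differed after prenatal testosterone. LOC114112267, an uncharacterised gene without a symbol, rose in the treated liver from a normalized read count of 0.440 ± 0.542 (SD, n = 4) to 56.4 ± 28.2 (SD, n = 5). Without control sheep 201 its control mean was 0.216. SLC25A45, a mitochondrial carrier gene, had 74.6 ± 12.2 (SD, n = 4) in control and 12.04 ± 5.32 (SD, n = 5) in treated liver, and HADHA, a subunit of the trifunctional protein of mitochondrial fatty acid oxidation, had 4027 ± 408 (SD, n = 4) and 2012 ± 325 (SD, n = 5). Of these genes, LOC114112267 passed the limma test, with a log2 fold change of 5.26 ± 0.51 (SE) and an adjusted p of 0.00285. It was 1 of 13640 genes tested, higher in 5 of 5 treated sheep than in any control. The control livers held 2 of its reads in all and the treated livers 261, a ratio of 133 after scaling, with an exact 95% interval of 36.4 to 1104 that covers counting error alone.

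No liver gene fell past the limma threshold. At an unadjusted p under 0.05 limma gave 296 lower and 248 higher genes, 544 together. The threshold alone would give 682, but other splits of the liver libraries gave a median of 338. Of 100 splits, the real one included, 28 gave at least 544, so chance is not excluded. The 544 became 1156 without control sheep 179, 829 without treated sheep 185, 1520 with array weights and 936 with all 19 libraries in 1 fit. By edgeR 1 gene passed, and by DESeq2 32 passed, 17 higher and 15 lower. The genes next to the limma threshold are given as values. SLC25A45 had a log2 fold change of -2.63 ± 0.38 (SE) and an adjusted p of 0.114 by limma and of 2.2e-07 by DESeq2. CD22, a B-cell receptor gene, had a mean of 53.9 in control and 10.2 in treated liver, CANT1, a nucleotidase gene, 1011 and 377, and NEB, the nebulin gene, 54.9 and 16.1. In the other direction LOC106990580 had 18.4 and 73.2, the long non-coding RNA LOC105608433 had 113 and 691, PRICKLE2, a planar cell polarity gene, had 153 and 466, and the long non-coding RNA LOC105609026 had 55.8 and 185. Without treated sheep 255 the treated mean of LOC105608433 was 439. The ranges of control and treated libraries did not overlap for any of these genes, and their limma adjusted p-values reached 0.835. They were named for small p-values, so the lack of overlap adds no support. These genes and HADHA were among the 32 that DESeq2 called, with DESeq2 adjusted p-values of 0.00135 for CD22, 0.00381 for HADHA and LOC105608433, 0.00434 for LOC106990580, 0.00832 for CANT1, 0.0233 for NEB and LOC105609026 and 0.0289 for PRICKLE2. In the liver simulation DESeq2 made 33 false calls, but beside its calls of the many changed genes, so that number cannot be set against the 32 real calls. The 32 real calls were not set against splits either, so they are weak evidence.

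**Figure D1:**
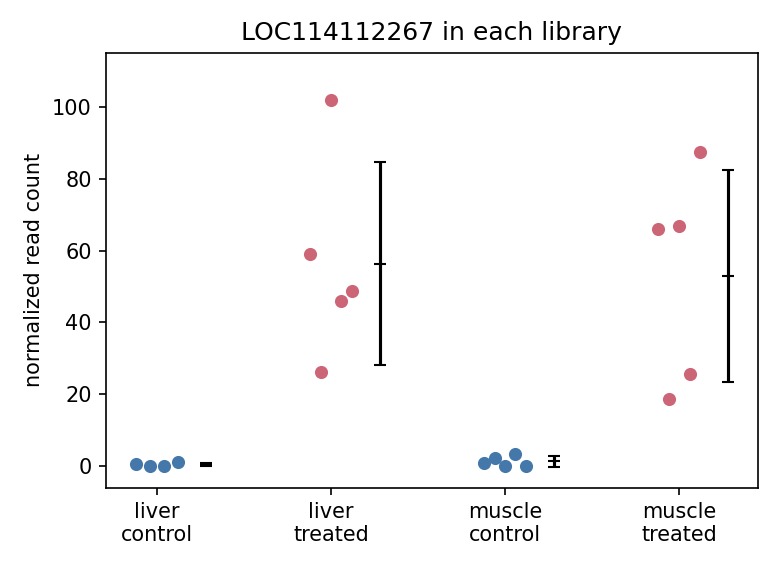
Normalized read count of LOC114112267 on the vertical axis for each library of the 4 groups, with points for libraries and bars for the mean ± SD. Treated libraries lie between 26.1 and 102 in liver and between 18.6 and 87.4 in muscle, and the highest control library has 3.48.

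Of the 12 liver lists called, 5 were lists of lipid genes, and these were lower in treated sheep. Genes of triglyceride synthesis and lipid droplets fell by a median of 0.70 on the log2 scale over 19 members, 16 of them below 0 (camera adjusted p = 2.3e-09). The call was lost with an estimated correlation, at an adjusted p = 0.169. PLIN2, which coats lipid droplets, had a mean of 3371 ± 2539 (SD, n = 4) in control and 878 ± 742 (SD, n = 5) in treated liver, G0S2, an inhibitor of triglyceride breakdown, had 2223 and 737, and MGLL, a monoglyceride lipase, had 958 and 394. Without treated sheep 63 the treated means were 557 for PLIN2 and 445 for G0S2. Without control sheep 179 the control mean of PLIN2 was 2131. Without treated sheep 233 the median of the list was -0.44. At an unadjusted p under 0.05, 8 members were lower and 0 higher, and 0 passed adjusted over the list alone. Genes of de novo lipogenesis fell by a median of 0.70 over 14 members (camera adjusted p = 1.2e-06), with an adjusted p = 0.217 with an estimated correlation. Of these, 5 were lower at an unadjusted p under 0.05 and 0 passed adjusted over the list alone. ME1, the cytosolic malic enzyme, had 135 and 32.7, ACACB, an acetyl-CoA carboxylase, had 594 ± 441 (SD, n = 4) and 229 ± 151 (SD, n = 5), and ACSS2, an acetyl-CoA synthetase, had 257 and 168. The control mean of ACACB was 374 without sheep 98.

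Genes of fatty acid oxidation and ketogenesis were lower as well, by a median log2 fold change of -0.26 over 23 members (camera adjusted p = 1.2e-06), which became an adjusted p = 0.217 with an estimated correlation. Of its members 19 were below 0, 8 were lower at an unadjusted p under 0.05, and 4 passed adjusted over the list alone. HADHA passed there with an adjusted p of 0.0116 by limma, SLC25A20, the carnitine carrier, with 0.0282 and means of 1247 and 671, and FGF21, a hepatic hormone of the fasting response, with 0.0367 and means of 613 and 170.2, the latter 90.8 without treated sheep 63. Genes of cholesterol synthesis and uptake had a median of -0.37 over 21 members (camera adjusted p = 1.4e-05), with an adjusted p = 0.226 with an estimated correlation. DHCR7, of the last steps of cholesterol synthesis, had 406 and 178, MVK, mevalonate kinase, had 473 and 252, and LSS, lanosterol synthase, had 512 and 325. Lipoprotein and cholesterol efflux genes had a median of -0.27 over 22 members (camera adjusted p = 2.3e-04), with an adjusted p = 0.169 with an estimated correlation. APOA5, an apolipoprotein of triglyceride clearance, had 11911 ± 383 (SD, n = 4) and 4607 ± 2599 (SD, n = 5), APOA4 had 823 ± 595 (SD, n = 4) and 196 ± 310 (SD, n = 5), and SOAT2, which esterifies cholesterol, had 1723 and 896. The treated mean of APOA4 was 63.3 without sheep 63. In both of these lists 5 members were lower at an unadjusted p under 0.05 and 0 passed adjusted over the list alone. In each of these 5 lipid lists the mean score was lower than the control mean in 5 of 5 treated sheep. The exact permutation p of these scores ran from 0.0159 for the triglyceride list to 0.0794 for cholesterol synthesis. After Benjamini-Hochberg adjustment over the liver lists these p-values ran from 0.224 to 0.373, so none passed. The groups still overlapped in de novo lipogenesis, where control 201 had -0.57 and treated 185 -0.40. Control 98, at 0.80, lifted the control mean of that list, and its other controls lay between -0.57 and -0.10. In cholesterol synthesis control 201 had -0.30, below treated 48 (-0.14) and treated 255 (-0.048). The groups did not overlap in the triglyceride, fatty acid oxidation and lipoprotein lists. Markers of adipocytes moved with the 5 lipid lists, with a median of -0.54 over 9 members (camera adjusted p = 0.00213, adjusted p = 0.200 with an estimated correlation). Of these, CIDEC, a lipid droplet gene, had 93.2 and 40.2, LPL, lipoprotein lipase, 40.4 and 23.0, and PLIN1 34.4 and 13.6. The control mean of PLIN1 was 22.9 without sheep 201.

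**Figure D2:**
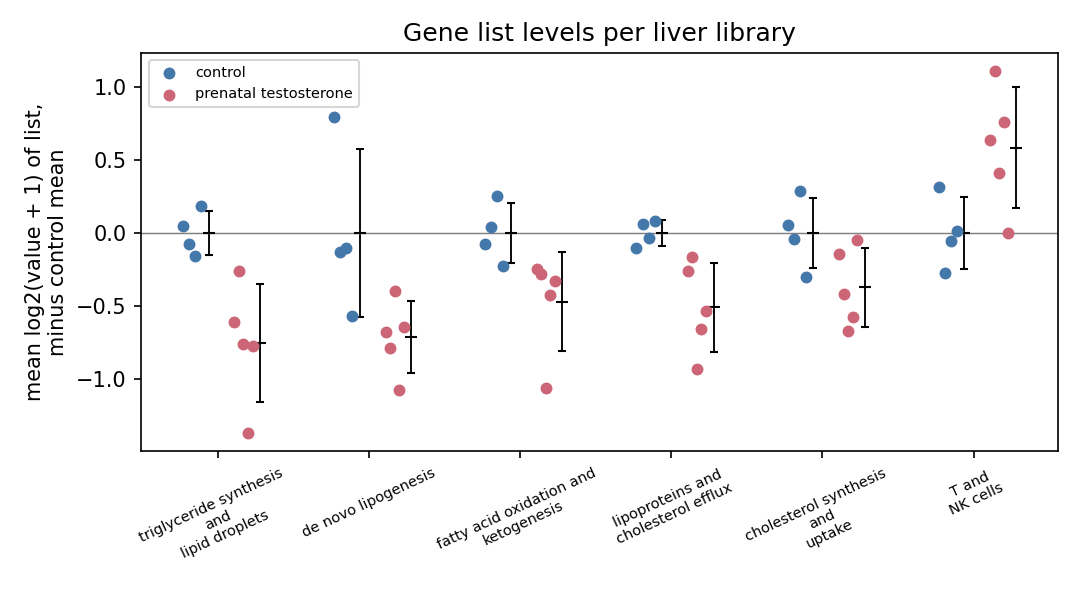
Mean log2(value + 1) of 6 of the gene lists past the camera threshold in each liver library, minus the control mean, with points for libraries and bars for the mean ± SD. In the lipid lists 5 of 5 treated libraries lie below 0. Control sheep 201 lies below treated sheep 185 in de novo lipogenesis and below treated sheep 48 and 255 in cholesterol synthesis.

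Immune lists moved in both directions in the liver. Markers of T and NK cells were higher by a median of 0.49 over 13 members, all 13 above 0 (camera adjusted p = 4.7e-06), with an adjusted p = 0.304 with an estimated correlation. The groups overlapped in the mean score of this list, where treated 255 had 0.0023, below control 98 (0.32) and control 201 (0.014). The exact permutation p of that score was 0.0397, and 0.233 after Benjamini-Hochberg adjustment over the lists. CD5, a T-cell surface gene, had 12.3 in control and 33.1 in treated liver, LCK, the kinase of the T-cell receptor, 27.1 and 54.2, and CD247, a chain of that receptor, 13.2 and 25.9. Inflammatory cytokine and NF-kB target genes had a median of 0.42 over 21 members (camera adjusted p = 0.0156, adjusted p = 0.595 with an estimated correlation), and among them CXCL9 had 90.3 and 237, IL1R1 1624 and 4256, and CXCL10 42.8 and 112. The median of that list was 0.27 without control sheep 131, 0.16 without 179 and 0.25 without 201, and 0.21 without treated sheep 185 and 0.18 without 233. Interferon-stimulated genes were lower, with a median of -0.30 over 25 members (camera adjusted p = 9.2e-04, adjusted p = 0.629 with an estimated correlation). Control sheep 98 stood 1.33 above the control mean of this list and the other controls between -0.69 and -0.0094, and without that sheep the median was -0.0089 and the call was lost (camera adjusted p = 0.911), as it was without treated sheep 185 (0.0508). The median was -0.60 without control sheep 131, -0.51 without control 201 and -0.51 without treated 63. ISG15, a ubiquitin-like antiviral protein, had 1156 ± 1259 (SD, n = 4) and 329 ± 307 (SD, n = 5), USP18, which removes it, 247 and 92.6, and ZBP1, a nucleic acid sensor, 440 and 172. Without control sheep 98 the control means were 531 for ISG15, 139 for USP18 and 232 for ZBP1, and without treated sheep 63 the treated mean of ISG15 was 193. At an unadjusted p under 0.05, 2 members of each of these 3 lists passed in its direction, and 0 passed adjusted over the list alone.

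Endoplasmic reticulum stress genes had a median of 0.21 over 20 members (camera adjusted p = 0.0336, adjusted p = 0.595 with an estimated correlation), 1 of them higher at an unadjusted p under 0.05 and 0 passing adjusted over the list alone. DDIT3, a stress transcription factor, had 114 and 207, MANF 1945 and 2769, and DNAJB9, a chaperone partner, 3789 and 5563. Gluconeogenesis genes had a median of -0.23 over 15 members (camera adjusted p = 0.0346, adjusted p = 0.541 with an estimated correlation). CREB3L3, a hepatic transcription factor, passed adjusted over the list alone at a limma adjusted p of 0.0413 with means of 5842 and 3178, while SLC37A4, the glucose-6-phosphate carrier, had 1225 and 770.0 and LDHB 5700 and 3742. Markers of skeletal muscle had a median of -0.27 over 6 members (camera adjusted p = 0.0304, adjusted p = 0.217 with an estimated correlation), and NEB passed adjusted over the list alone at a limma adjusted p of 0.00468. TTN had 17.8 ± 17.5 (SD, n = 4) and 5.41 ± 3.75 (SD, n = 5) there, with a control mean of 9.68 without sheep 201, and CASQ1 had 14.2 and 10.2. In all, camera at the preset correlation called 12 of 47 lists, 9 lower and 3 higher, and 0 were called with an estimated correlation or by fry's directional test, while fry's mixed test, for change in either direction, called 2, fatty acid oxidation and adipocytes. The gluconeogenesis call was lost without control 179, control 201, treated 185 or treated 233 (camera adjusted p from 0.146 to 0.289) and with no filter (0.204), that of endoplasmic reticulum stress without control 131, control 179, treated 185 or treated 233, and that of skeletal muscle without any 1 of these 4 sheep, or without control 201. Without 1 library the median of gluconeogenesis was -0.091 (treated 185), -0.12 (treated 233) or -0.44 (treated 255), that of endoplasmic reticulum stress 0.11 (control 131) or 0.13 (treated 233), and that of skeletal muscle -0.15 (control 201), -0.46 (treated 48) or -0.42 (treated 185). The inflammatory call was lost without control 179, treated 185 or treated 233 and that of adipocytes without control 179 or treated 185, and the 5 lipid lists and the T and NK cell list were called without each library in turn.

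Of the fixed hormone, insulin and energy genes reported for liver, none passed the limma test, and each had an adjusted p of 0.999. SREBF1, a regulator of lipogenesis, had a mean of 203 in control and 106 in treated liver, and CPT1A, which admits fatty acids to mitochondria, 3928 and 2598. INSR, the insulin receptor, had 1327 and 1359, IRS1, its substrate, 331 and 335, IGF1 4269 and 4162, PCK1, of gluconeogenesis, 10442 and 12193, FASN, fatty acid synthase, 49.5 and 41.7, ESR1, the estrogen receptor, 1669 and 1824, and NR3C1, the glucocorticoid receptor, 994 and 1009.7. IRS2 had 102 and 131, PPARGC1A 298 and 277, SCD 23.6 and 8.76, and ADIPOR2 131 and 109. For SCD the control mean was 14.9 without sheep 98 and the treated mean 5.26 without sheep 255. The control and treated ranges overlapped for each of these genes.

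The second comparison asked the same of muscle. LOC114112267 rose in treated muscle too, from 1.33 ± 1.499 (SD, n = 5) to 52.9 ± 29.5 (SD, n = 5). Its control mean was 0.789 without sheep 179. It had a log2 fold change of 4.56 ± 0.56 (SE) and a limma adjusted p of 0.0192. CNTROB, a centriole gene, had 142 ± 16.4 (SD, n = 5) in control and 253 ± 30.1 (SD, n = 5) in treated muscle, and SNTB1, a syntrophin of the dystrophin complex, had 5799 ± 591 (SD, n = 5) and 3358 ± 580 (SD, n = 5), neither past the limma threshold. LOC114112267 was 1 of 12966 genes tested and was higher in 5 of 5 treated sheep than in any control. Its reads numbered 6 in control and 300 in treated muscle, a ratio of 38.2 after scaling with an exact 95% interval of 17.4 to 105. By limma its call was lost without control sheep 98 (adjusted p = 0.0756), control sheep 201 (0.0574), treated sheep 48 (0.0811) or treated sheep 185 (0.172), and with a pseudocount of 0.25 (0.102).

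No muscle gene fell past the limma threshold, while 1862 genes had an unadjusted p under 0.05 by limma, 955 higher and 907 lower. The threshold alone would give 648, and other splits of the muscle libraries gave a median of 596. With all 19 libraries in 1 fit the 1862 became 865. By edgeR 1 gene passed and by DESeq2 259 passed, 164 higher and 95 lower. Next to the limma threshold, each at an adjusted p of 0.104, stood CNTROB, DDX11, a DNA helicase gene with means of 66.3 and 147, HSF4, a heat shock transcription factor with 515 and 1049, and LOC114118399 with 107 and 207. The lower ones at the same limma adjusted p were SNTB1, RPS3, a ribosomal protein gene with 1202 and 523, FBXL17, an F-box gene with 1943 and 1263, NUP58, a nuclear pore gene with 283 and 177, and EPM2A, the laforin gene of glycogen metabolism, with 1074 and 717. The ranges of control and treated muscle overlapped for RPS3 alone among these 9 genes, which were named for small p-values, so this adds no support. All 9 were among the 259 that DESeq2 called, with DESeq2 adjusted p-values from 1.2e-04 for CNTROB to 0.00131 for NUP58. In the muscle simulation DESeq2 made 31 false calls beside its calls of the many changed genes, so that number cannot be set against the 259 real calls.

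The muscle lists called were lists of energy metabolism, contractile and proteolysis genes, which were lower, and of satellite cell and immune genes, which were higher. Glycolysis genes fell by a median of 0.41 on the log2 scale over 21 members, 20 of them below 0 (camera adjusted p = 3.1e-04), with an adjusted p = 0.712 with an estimated correlation. PGK1, a glycolytic kinase, had 8501 and 5424, and PDHA1 with 10924.5 and 6407 and PDHB with 3414 and 2554 are subunits of pyruvate dehydrogenase. Citrate cycle genes had a median of -0.35 over 15 members, 14 of them below 0 (camera adjusted p = 4.3e-04, adjusted p = 0.712 with an estimated correlation). The estimated correlation of this list was 0.74, far above the preset 0.01. Its mean score was below the control mean in 4 of 5 treated sheep. Treated 63 had 0.19 and control 132 had -0.39 (exact permutation p = 0.111 for the score). SUCLG2, a succinyl-CoA ligase subunit, had 3786 and 2705, DLD, dihydrolipoamide dehydrogenase, 6424 and 4429, and CS, citrate synthase, 6076 and 4419.8. Oxidative phosphorylation genes of the nucleus had a median of -0.13 over 53 members, 47 of them below 0 (camera adjusted p = 0.00461, adjusted p = 0.929 with an estimated correlation). This is close to the median of -0.11 of the 4322 genes of highest abundance in muscle, so it is not shown to be a change of this list apart from its level. It was -0.023 without control sheep 131, -0.21 without control 201, -0.21 without treated 63 and -0.079 without treated 255. ATP5MC2, of ATP synthase, had 567 and 459, NDUFS1, of complex I, 5553.5 and 3811, and SDHC, of succinate dehydrogenase, 3446 and 2598. Genes of mitochondrial biogenesis and dynamics had a median of -0.20 over 20 members (camera adjusted p = 0.0143, adjusted p = 0.712 with an estimated correlation), among them TFB1M, with 71.6 and 53.5, and TFB2M, a mitochondrial transcription factor, with 626 and 509. Its median was -0.11 without control sheep 131, and that of the citrate cycle was -0.54 without treated sheep 63. At an unadjusted p under 0.05 the lower members numbered 6 in glycolysis, where 1 was higher, 4 in the citrate cycle and 2 in each of the other lists, and in none of these 4 lists did any member pass adjusted over the list alone.

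Fast fibre genes had a median of -0.45 over 15 members (camera adjusted p = 0.00567), with an adjusted p = 0.712 with an estimated correlation. TPM1, a tropomyosin, had 64646 and 46343, MYBPC2, fast myosin-binding protein, 63728 and 42621, and ACTN3, fast-fibre actinin, 29549 and 20878. Markers of skeletal muscle itself had a median of -0.43 over 12 members, all 12 below 0 (camera adjusted p = 0.0121, adjusted p = 0.712 with an estimated correlation), with NEB at 123872 and 90532, CASQ1, a calcium store protein, at 19080.5 and 14302, and ACTN2 at 50847 and 39196. Atrophy and proteolysis genes had a median of -0.22 over 20 members (camera adjusted p = 0.0294, adjusted p = 0.712 with an estimated correlation). FOXO3, a transcription factor of muscle protein breakdown, passed adjusted over the list alone at a limma adjusted p of 0.0115, with 5195 ± 1716 (SD, n = 5) in control and 2756 ± 262 (SD, n = 5) in treated muscle. FOXO1 had 1133 and 739 and USP14, a deubiquitinase of the proteasome, 1139 and 859. Of the fast fibre and skeletal muscle lists 0 members passed adjusted over the list alone. Without treated sheep 48 the medians were -0.25 for fast fibre and -0.27 for skeletal muscle, and without treated sheep 255 that of atrophy was -0.35. Adipocyte markers had the lowest median of the 42 muscle lists, -0.67 over 8 members, 7 of them below 0, and 2 passed adjusted over the list alone. That list was not called (camera adjusted p = 0.0577, adjusted p = 0.712 with an estimated correlation). It was called with no filter, TMM or cyclic loess (0.0333) and without control 98, control 131, control 179, treated 48 or treated 185.

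Myogenesis and satellite cell genes were higher by a median of 0.37 over 13 members, 12 of them above 0 (camera adjusted p = 0.00567), with an adjusted p = 0.712 with an estimated correlation. Adjusted over the list alone, 3 passed limma, PAX7, the satellite cell transcription factor, with 15.1 ± 7.198 (SD, n = 5) and 43.5 ± 16.2 (SD, n = 5) at an adjusted p of 0.0141, CDH15, M-cadherin, with 179.8 and 253 at 0.0141, and MYF5, a myogenic factor, with 15.6 and 32.8 at 0.0330. Antigen presentation genes had a median of 0.28 over 10 members, all 10 above 0 (camera adjusted p = 0.00956, adjusted p = 0.712 with an estimated correlation), with CIITA, the regulator of class II genes, at 10.2 and 24.4, NLRC5, the regulator of class I genes, at 175 and 225, and PSMB9, of the immunoproteasome, at 61.7 and 83.3. Markers of T and NK cells had a median of 0.39 over 11 members (camera adjusted p = 0.0155, adjusted p = 0.712 with an estimated correlation), with LCK at 17.8 and 32.1, CD3D, of the T-cell receptor, at 16.4 and 24.3, and NKG7, a gene of cytotoxic granules, at 30.6 and 43.2. In the antigen presentation and T and NK cell lists 0 members passed adjusted over the list alone. The median of myogenesis was 0.24 without control sheep 132 and 0.24 without treated sheep 233, and that of antigen presentation 0.19 without treated 233. In all, camera at the preset correlation called 10 of 42 lists, 7 lower and 3 higher, and 0 were called with an estimated correlation or by fry's directional test, while fry's mixed test, for change in either direction, called none of the 10. It called 5 other lists, adipokine signalling (fry's mixed adjusted p = 0.00414), epigenetic modifiers (0.00494), and glycogen metabolism, insulin signalling and triglyceride synthesis and lipid droplets (0.0353 each). Of adipokine signalling 4 of 10 members passed adjusted over the list alone, and its median was -0.21. In that list 5 of 5 treated sheep were below the control mean of its score (exact permutation p = 0.00794, and 0.333 after Benjamini-Hochberg adjustment over the lists). Under cyclic loess scaling, chosen after seeing the data, 6 lists were called and 4 of the 10 were among them, while the calls of oxidative phosphorylation, mitochondrial biogenesis, fast fibre, skeletal muscle, atrophy and T and NK cells were lost (camera adjusted p from 0.149 to 0.933). With that scaling the median was -0.11 for fast fibre, -0.060 for skeletal muscle, -0.19 for glycolysis and -0.17 for the citrate cycle. It stayed at 0.37 for myogenesis and 0.28 for antigen presentation. The falls of the fast fibre and skeletal muscle lists are therefore not shown apart from gene level, and those of glycolysis and the citrate cycle only in part. The glycolysis, citrate cycle and fast fibre lists were called without each library in turn, and each of the other 7 was lost without at least 1 library, atrophy without control 98, control 201, treated 185 or treated 233, T and NK cells without control 201, treated 48 or treated 233, oxidative phosphorylation without control 131 or treated 255, mitochondrial biogenesis without control 131 or treated 185, skeletal muscle without treated 48 or treated 255, myogenesis without control 132 and antigen presentation without treated 233.

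**Figure D3:**
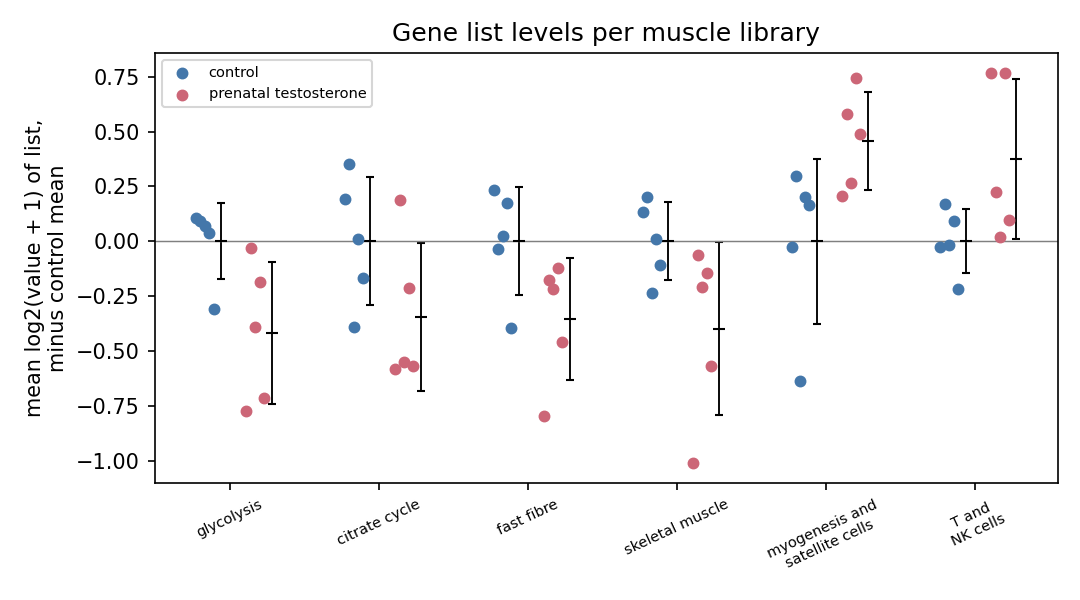
Mean log2(value + 1) of 6 of the gene lists past the camera threshold in each muscle library, minus the control mean, with points for libraries and bars for the mean ± SD. In the glycolysis and fast fibre lists 5 of 5 treated libraries lie below 0. In glycolysis control sheep 201 lies below treated sheep 63 and 233.

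Of the fixed genes reported for muscle, PIK3R1, the regulatory subunit of the insulin-responsive PI3 kinase, had 5461 ± 959.8 (SD, n = 5) in control and 3359 ± 492 (SD, n = 5) in treated muscle, a log2 fold change of -0.70 ± 0.15 (SE) with a limma adjusted p of 0.125 and a DESeq2 adjusted p of 0.00255. None of the others passed limma, edgeR or DESeq2, and their ranges overlapped. CPT1B, which admits fatty acids to muscle mitochondria, had 2623 and 3604, INSR 1268 and 1308, IRS1 753 and 869, SLC2A4, the insulin-responsive glucose transporter, 1090.0 and 911, GYS1, glycogen synthase, 4385 and 3586, ESR1 623 and 481, NR3C1 2233 and 2067, MSTN, the growth inhibitor myostatin, 738 and 661, PPARGC1A 368 and 273, ADIPOR1 1093 and 997, and MYH2, a fast myosin, 89499 and 69880.3.

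More genes were detected in treated muscle. At 8000000 reads a treated muscle library held 17017 ± 274 genes (SD, n = 5) and a control library 16473 ± 31.9 (SD, n = 5), and 5 of 5 treated libraries exceeded each control (exact two-sided permutation p = 0.00794, the smallest this design allows, and 0.0198 after Benjamini-Hochberg adjustment over 10 library comparisons). The share of reads taken by the 10 most abundant genes was 17.0% ± 2.12 (SD, n = 5) in treated and 19.1% ± 0.801 (SD, n = 5) in control muscle (exact permutation p = 0.0397, adjusted 0.0794). By level, the 4322 genes of lowest abundance in muscle had a median log2 fold change of 0.14 and the 4322 of highest abundance -0.11. In liver the numbers at equal depth were 17077 ± 391 (SD, n = 5) in treated and 18038 ± 1411 (SD, n = 4) in control sheep (exact permutation p = 0.111), and control sheep 201 alone held 20124.

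**Figure D4:**
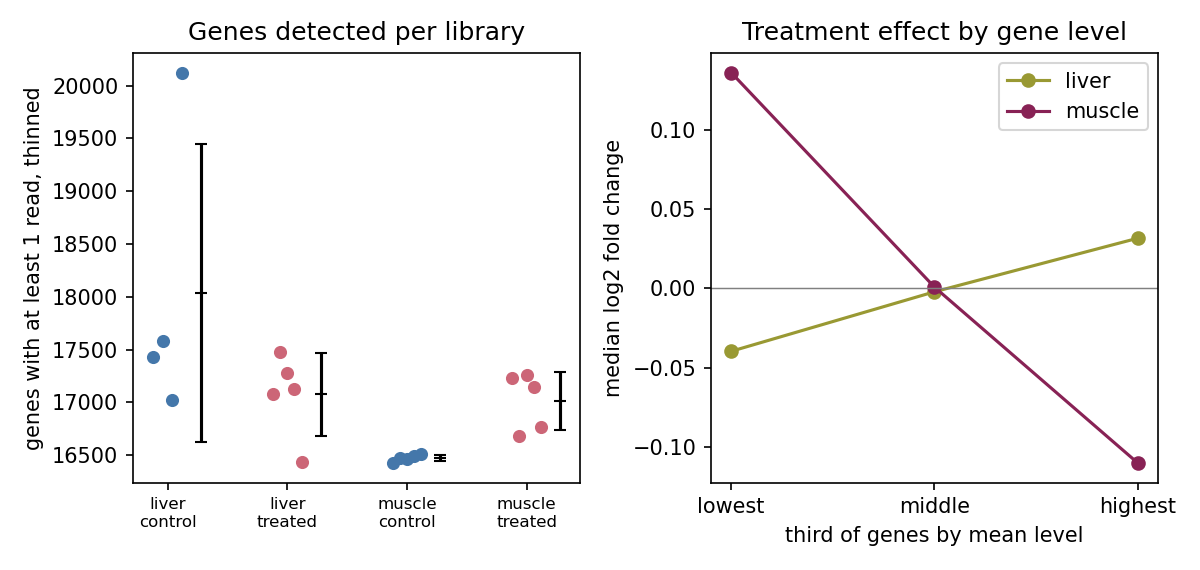
Genes detected per library at equal depth (left, points for libraries and bars for the mean ± SD), and median log2 fold change of the genes grouped by level (right). Treated muscle libraries hold 16680 to 17260 genes and control muscle libraries 16425 to 16511.

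The third comparison asked whether the treatment effect differed between liver and muscle. TMEM82, a transmembrane protein gene, was lower in treated liver and higher in treated muscle. In liver it had 521 ± 81.8 (SD, n = 4) in control and 303 ± 95.2 (SD, n = 5) in treated sheep, and in muscle 32.9 ± 2.69 (SD, n = 5) and 70.0 ± 14.0 (SD, n = 5). It was the 1 gene of 11697 whose effect differed by limma, by 1.87 ± 0.30 (SE, muscle minus liver, log2), with an adjusted p of 0.0497. With the sheep as a fixed block the limma adjusted p was 0.236 and the call was lost, and it was lost without any 1 sheep other than sheep 63, at up to 0.418. At an unadjusted p under 0.05 limma gave 573 genes, where the threshold alone would give 585 (1461 without sheep 179, 810 without sheep 185, 1669 with array weights). By edgeR 1 gene was called and by DESeq2 14.

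Lipid lists shifted differently between the tissues in a test added after seeing the data. Camera called 6 of 35 lists, and 0 with an estimated correlation. With the sheep as a fixed block it called 7, of which 5 were among the 6, and the fatty acid oxidation list was lost at a camera adjusted p of 0.279. The triglyceride and lipid droplet list had a median of -0.70 in liver and 0.07 in muscle, a median difference of 0.74 (camera adjusted p = 3.2e-05, adjusted p = 0.196 with an estimated correlation). De novo lipogenesis genes had -0.70 and -0.05, a difference of 0.65 (camera adjusted p = 8.1e-05, adjusted p = 0.283 with an estimated correlation). Cholesterol synthesis genes had -0.37 and -0.04 (camera adjusted p = 0.0315, adjusted p = 0.740 with an estimated correlation) and fatty acid oxidation genes -0.22 and -0.14 (0.0416, and an adjusted p = 0.896 with an estimated correlation). Glycolysis genes had -0.12 in liver and -0.40 in muscle (camera adjusted p = 0.0315, adjusted p = 0.879 with an estimated correlation), and glucose uptake genes 0.12 and -0.13 (0.0315, and an adjusted p = 0.283 with an estimated correlation).

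The effects of treatment in the tissues were weakly correlated across genes. Spearman's rho over 11697 genes, which are not independent replicates, was 0.108, and 52 of 100 reassignments of the sheep gave a rho as high. At an unadjusted p under 0.05 in both tissues there were 78 genes, of which 39 were higher in both, 22 lower in both and 17 opposite. Both tissues came from the same sheep, so the 55.1 of independent lists is not the number without a treatment effect, and 14 of 100 reassignments of the sheep, the real one included, gave as many genes.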

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

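The tests of depth, of on and off genes, of other cell types, of list differences and of genes shared between tissues were chosen after the results were seen.

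LOC114112267 was on in the 5 treated sheep and nearly silent in the controls in both tissues. For reads shared with another annotated gene, 0 other genes correlated with it above 0.9 in both tissues, and the highest reached 0.871. That margin is narrow, and a gene that lends only part of its reads need not correlate so closely. This explanation therefore stays open. An inherited on or off difference between sheep stays open and may account for it, since 9 other genes were on or off by sheep in both tissues at other divisions of the 9 sheep, although 4 of the 10 such genes parted them 5 to 4 and 126 divisions of that kind are possible, so that few would fall on the treatment groups. As many calls in liver came from 12 of 100 splits, with 1 gene for the real split and up to 1898 for another, and in muscle from 7 of 100, with 1 and up to 38, so chance is not excluded for the number of calls in either tissue. These splits counted calls and did not ask whether a gene parts the groups in both tissues. They therefore decide nothing about chance for LOC114112267 itself. The split with 1898 genes points to a structure among the liver libraries. An effect of prenatal testosterone stays open too and was not tested apart from these.

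More genes were detected in treated muscle. Sequencing depth is argued against, since at equal depth the lowest treated library held 169 more genes than the highest control library. A few abundant genes taking the reads are argued against too, since without the 50 most abundant genes, at a lower depth of 5000000 reads, that gap was 143. A larger share of all other cell types was predicted to raise T and NK cell and adipocyte markers alike. Their effects moved apart by 2.80 standard errors, with adipocyte markers at a median of -0.67 (camera adjusted p = 0.0577). Both directions were known when this was predicted, and the standard error took both scores as independent, so nothing is concluded. T and NK cell markers had a median of 0.39 and skeletal muscle markers -0.43. The medians were 0.06 for macrophages, 0.04 for fibroblasts, -0.03 for endothelial cells and -0.14 for smooth muscle and pericytes. A larger share of T and NK cells and a smaller share of adipocytes were not tested and stay open. RNA quality stays open, as does a biological effect of the treatment, and of its signs the cytosolic ribosomal list had a median of 0.07 (camera adjusted p = 0.0660, called under TMM and cyclic loess), immediate early genes -0.12 (0.529) and heat shock genes 0.04 (0.667).

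The liver library of control sheep 201 held more genes than any other liver library, 20704 against 17930 to 18289 in its group, with a gap ratio of 0.871. Depth is argued against, since at equal depth it exceeded the next liver library by 2545 genes. Muscle in the sample is argued against, since 84.8% of the genes it alone held with at least 3 reads were near silent in muscle. A low even background over the whole annotation was left open, because the 1024 genes seen in it alone, 9.75 times the 105 of the next library, restate the pattern and would follow from any source of extra genes. Without this library the liver call of LOC114112267 kept a limma adjusted p of 0.00803 and 13 lists were called; no biological explanation was tested.

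Single libraries far from their group were found in 10 of 232 groups tested, where chance gives about 12. The gap to the nearest library as a share of the group's range was 0.947 for ACACB (sheep 98, 1255 against 360 to 384, with a mean of 594 and of 374 without it) and 0.854 for APOA5 (sheep 98) in control liver. In sheep 201 it was 0.833 for CANT1 and 0.834 for SLC25A20. In treated liver it was 0.806 for HADHA, 0.774 for SLC37A4 and 0.753 for LCK, each in sheep 255, and 0.767 for CXCL9 in sheep 185 (56.7 against 222 to 335). In treated muscle it was 0.742 for NEB in sheep 48.

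Effects that differed between the tissues, as muscle minus liver on the log2 scale, were 1.87 for TMEM82 and list medians of 0.74 for triglyceride synthesis and lipid droplets, 0.65 for de novo lipogenesis, 0.21 for cholesterol synthesis and uptake, 0.10 for fatty acid oxidation and ketogenesis, -0.26 for glycolysis and -0.20 for glucose uptake. Genes at an unadjusted p under 0.05 in both tissues numbered 78, and 61 of them moved the same way; 14 of 100 reassignments of the sheep gave as many, with up to 396, and 14 of 100 as many in the same direction, with up to 378, so chance is not excluded. As many genes whose effect differed came from 6 of 100 reassignments of the sheep, with 1 gene in the real assignment and up to 548 in another, and as many lists from 41 of 100, with 6 and up to 13, so chance is not excluded for either.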

How the results depend on the processing

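Cyclic loess scaling and the tests of list differences, long non-coding RNAs and genes detected were chosen after the results were seen. The 1 gene in liver stayed 1 with other pseudocounts, no filter, TMM, robust shrinkage, edgeR and each library left out; it became 0 at a mean of at least 50, where LOC114112267 is no longer tested, 2 with array weights, which add SLC25A45, 9 with all 19 libraries in 1 fit and 32 by DESeq2. The 1 gene in muscle became 0 with a pseudocount of 0.25 and at a mean of at least 50, 259 by DESeq2, and 0 to 4 with 1 library left out: 0 without control 98, control 201, treated 48 or treated 185, 2 without control 132 and 4 without treated 255. The 1 gene that differed between tissues, TMEM82, became 0 with a pseudocount of 4, no filter, robust shrinkage and the sheep as a fixed replicate block, 3 with array weights, 14 by DESeq2, and 0 to 1 with 1 sheep left out, where it was kept without sheep 63 alone. Its difference stayed between 1.65 and 2.09 throughout, and with the sheep as a random block its limma adjusted p was 0.0276. The 12 liver lists became 0 with an estimated correlation and 0 by fry's directional test, and 8 to 20 with 1 library left out, 20 without treated 255. The 10 muscle lists became 0 with an estimated correlation and 0 by fry's directional test, 17 with no filter, and 6 with cyclic loess. The 6 list differences became 0 with an estimated correlation, 7 with the sheep as a fixed block, and 3 to 10 with 1 sheep left out, 3 without 179 or 185 and 10 without 201. The correlation between tissues stayed between 0.0193 and 0.198. Of 1182 gene and setting pairs in liver 1151 kept direction and side of the threshold, 15 passed it and 16 reversed, and of 1115 in muscle 1089 kept both, 15 passed, 5 no longer passed and 6 reversed. Genes that reversed did not pass the test in either direction. IGF1 in liver was -0.052 by edgeR and -0.037 by DESeq2, IRS1 in liver 0.014 by DESeq2, and NR3C1 in muscle 0.034 with cyclic loess. With 1 library left out, liver log2 fold changes ran from -0.30 to 0.13 for IRS1, -0.36 to 0.43 for IGF1, -0.019 to 0.088 for INSR, -0.13 to 0.29 for NR3C1, -0.72 to 0.025 for PPARGC1A, -0.065 to 0.23 for ESR1, -0.49 to 0.21 for FASN and -0.067 to 0.33 for PCK1. In muscle they ran from -0.53 to 0.022 for MSTN and -0.034 to 0.17 for INSR, and the median of long non-coding RNAs in liver ran from -0.043 to 0.12. Apart from the named constructions the cause was not tested. Median-of-ratios rescaling repeats the deposited scaling and tests nothing. Depth limits the fold change of LOC114112267, whose control reads numbered 2 in liver and 6 in muscle.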

Other observations

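The sets of long non-coding RNAs and of genes by level were chosen after the data were seen, and the number of splits for the DESeq2 genes was raised after its first outcome was seen.

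Long non-coding RNAs were higher as a set in treated muscle. Their median log2 fold change was 0.20 over 275 genes, with 40 higher and 3 lower at an unadjusted p under 0.05 (camera p = 1.6e-05, and p = 0.0128 with an estimated correlation). That median exceeded 99.99% of 10000 random lists matched on level, the middle 95% of which had medians between 0.05 and 0.16. With cyclic loess it was 0.09, with p = 0.0236 and p = 0.297 with an estimated correlation. Of 100 splits of the muscle libraries 1, the real one, gave as large a median, 0.203854, but the next gave 0.202993, so the margin is narrow and chance is not firmly excluded. The liver set of 328 genes had a median of 0.04 and did not pass camera, but that median too exceeded 99.17% of matched lists, the middle 95% of which had medians between -0.079 and 0.030.

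In muscle 1862 genes had an unadjusted p under 0.05, and of 100 splits 1, the real one, gave as many, while another gave 1785. The 100 were drawn from 126 possible splits, and several patterns were set against splits without adjustment. The number was thus rare among splits, but by a narrow margin, and chance is not firmly excluded. The 259 genes by DESeq2 were reached by 2 of 100 splits, the real one included, with up to 360 in another. That test was first drawn with 40 splits, of which 2 gave as many, a share that does not exclude chance. The number of splits was raised to 100 after that outcome was known, so the lower share rests on the larger draw, and chance is not firmly excluded. The 10 muscle lists were matched by 49 of 100 splits, with up to 20, and the 12 liver lists by 31 of 100, with up to 26, so chance is not excluded for either. The correlation between tissues of 0.108 was matched by 52 of 100 reassignments, with up to 0.430, and chance is not excluded for it either.

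The difference of 0.247 between the genes of lowest and highest level in muscle was reached by 2 of 100 splits, the real one included, with up to 0.264 in another. The first principal component of liver held 41.0% of the variance and did not follow treatment (exact permutation p = 0.667), while the second held 13.5% (exact permutation p = 0.0397). In muscle the second held 16.9% and parted the groups (exact permutation p = 0.00794, the smallest the design allows), while the first held 19.5%.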
